A study of Mus musculus with 3 samples.

How the data were processed

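RNA was extracted from spleen T cells activated in culture, and libraries were made from 500 ng of total RNA with a SMARTER mRNA kit, per the labels' protocols. Culture was for 3 days with antibody against CD3 at 2 ug/ml, antibody against CD28 at 5 ug/ml and interleukin 2 at 100 IU/ml in medium with 10% serum. Per the submitters' processing notes, STAR, Partek and the mouse build mm10 were used, and versions, roles and the annotation release are not given in the sources used here. The strand setting of the counting is not given either, so genes that overlap on opposite strands cannot be told apart.

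The deposited table is named as raw counts, but its values are CPM (reads scaled to a total of 1000000 per library): each column has that sum. Low values repeat at a fixed step, the worth of 1 read, which gave the estimated depths of 41.0, 17.3 and 13.9 M reads for the young, aged vehicle and aged fumarate libraries. With a tolerance of 0.02 reads, 60.0% to 68.4% of genes sat at whole reads, and the others fell between, as when reads that fit several genes are shared by estimation. Whole reads were therefore not recovered and no count model was fitted. Every listed gene had at least 10 estimated reads over the 3 libraries, so genes below that are not in the table. A value of 0 allows up to 3 reads, or 0.0732, 0.174 and 0.217 CPM in the young, vehicle and fumarate libraries. Pseudogenes took 10.2%, 8.32% and 8.79% of CPM and mitochondrial transcripts 1.33%, 2.01% and 1.72%. Gene positions are those of the table, with the end moved back by 1 base, after which 17191 of 17355 symbols found in GENCODE M21 had the same position.

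The 3 groups were taken from the titles. The age is stated as 24 months for the aged mice, without saying whether at the start or the end of the 2 months of treatment, and the young mice are labelled vehicle without a stated course. The 3 pairs of libraries were compared. The plan, made before the data were examined, was for counts scaled by the trimmed mean of M values (TMM) with a minimum of 50 counts and exact counting intervals, and for the log2 of value + 1 with no interval and the same fold limit if the table held normalized values. The second form is used here, with CPM + 1 and a limit of 2-fold. That it drops the TMM scaling and the minimum of 50 is a reading of the plan made once the unit was known, and both are given as alternatives. The 95% Clopper-Pearson intervals were added on estimated reads and cover counting error alone, since reads are not independent molecules. They excluded no difference for every gene counted as 2-fold and for all 918 list members past 1.5-fold over lists and comparisons.

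Gene lists, 47 in all, covering T cell states, metabolism, stress responses, cell division and markers of other cell types, were fixed before the data were examined. A list is described by its median log2 ratio, by how many members with a mean of at least 1 CPM lay past 1.5-fold, and by the percentile of its median among 10000 random lists of the same size matched on expression in 20 bins, given for lists of at least 5 measured members. For fumarate over vehicle, random lists were also matched on the ratio of aged vehicle over young, which was chosen after seeing the data. Percentiles describe these libraries and are not p-values. Genes named in the text follow a rule also fixed beforehand: the 12 highest and 12 lowest genes per comparison without receptor segments, predicted, mitochondrial, sex-linked and histone genes and pseudogenes, up to 4 members per list with the largest ratio, 27 of 28 key genes that the table holds, and 8 genes per library that stands apart with at least 200 reads. Genes were ranked by the log2 ratio of CPM + 1 in place of the planned interval bound, again because of the unit. Positions are given for a few of them, and 1 key gene is not reported here.

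The gene counts were tested on simulated reads with 200 changed genes among 17796, drawn above an expression minimum and with counting error alone. Changes in low genes and spread between mice were therefore not covered, and the intervals were not tested on these reads. At 2.5-fold, 96.5% were recovered for aged vehicle over young, 95.0% for fumarate over vehicle and 99.0% for fumarate over young, and at 4-fold 99.5%, 100% and 100%. Of the unchanged genes 1 was counted, for fumarate over vehicle at 4-fold. Alternatives were TMM (trims of 30% and 5%), median-of-ratios and upper-quartile scaling, read minimums of 50 and 200, a 3-fold limit, thinning to the smallest library, leaving out receptor segments, mitochondrial and ribosomal protein genes, and other expression minimums. Added after seeing the data were protein-coding genes alone, scaling to the T cell identity list and, for the gene counts and the library that stands apart, other constants than 1 CPM and minimums of 10 CPM. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.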

Results

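Spleen T cells of C57BL/6 mice were activated in culture for 3 days with plate-bound antibodies against CD3 and CD28 in the presence of interleukin 2, and their polyadenylated RNA was sequenced. The 3 libraries came from young mice aged 2 months, from aged mice given vehicle and from aged mice given fumarate, an intermediate of the tricarboxylic acid cycle. The age stated for the aged mice was 24 months, and the fumarate dose was 10 mg/kg, given 3 times a week for 2 months before the cells were taken. Each group had 1 library, and the labels do not say whether several mice were pooled, so no difference below has a replicate check or a p-value. Depth was estimated at 41.0 M reads for the young, 17.3 M for the aged vehicle and 13.9 M for the aged fumarate library. Values are CPM, reads per gene scaled to the same total in each library, differences are log2 ratios of CPM + 1, and the 95% intervals cover counting error alone and belong to the log2 ratio of CPM without the added 1. The added 1 makes ratios of low genes smaller than their plain CPM ratio.

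The first comparison set aged vehicle against young T cells and asks how the activated cells differed with age. Of 17796 genes, 1595 were at least 2-fold higher and 304 at least 2-fold lower in the aged vehicle library. The genes with the highest ratios included genes of other blood lineages. Csf2rb, the shared beta chain of the receptors for interleukin 3, interleukin 5 and GM-CSF (chromosome 15, 78325752 to 78353847, mm10), was at 0.651 CPM in the young and 536 CPM in the aged vehicle library. Its near-identical neighbour Csf2rb2 went from 0.325 to 399.6 CPM, and how reads were divided between these 2 genes is uncertain. Pf4, which encodes platelet factor 4 (chromosome 5, 90772435 to 90773383), was at 3.17 and 468 CPM, a log2 ratio of 6.81 with an interval of 6.96 to 7.47. Itga2b, the alpha chain of the platelet fibrinogen receptor, was at 3.42 and 416 CPM, and Vwf, which encodes von Willebrand factor, at 0.732 and 143 CPM. Gata2, a transcription factor of blood progenitors and mast cells, was at 0.122 and 113 CPM.

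As lists, all 11 measured erythroid and platelet markers and all 10 measured basophil and mast cell markers were at least 1.5-fold higher in the aged vehicle library, with median log2 ratios of 5.21 and 4.96. Mcpt8, a basophil protease, was at 0.122 and 86.7 CPM, and Cpa3, a mast cell carboxypeptidase, at 0.0976 and 64.1 CPM. Of the B cell markers, 9 of 12 were higher (median 1.35), as were 7 of 12 plasma cell markers (median 1.40, or 0.154 and inside the range of random lists without receptor segments) and 9 of 10 macrophage and monocyte markers (median 2.20, with 1 lower). The T cell identity list was lower by a median of −0.33, with 1 of 18 members past 1.5-fold (Cd2, 327 and 198 CPM). These levels are measured facts of the aged vehicle library and stand beside each list described for it below.

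**Figure D1:**
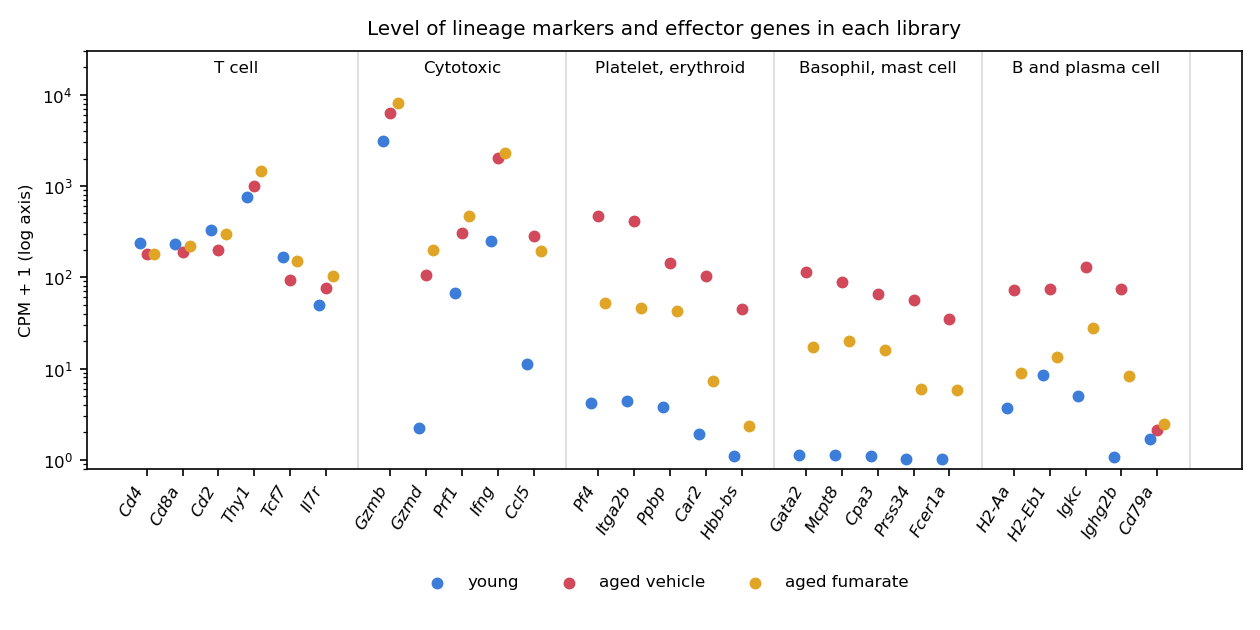
CPM + 1 on a log axis for T cell genes, cytotoxic genes and markers of other lineages, with 1 point per library (young, aged vehicle, aged fumarate). Pf4 was at 3.17, 468 and 51.3 CPM and Gzmb at 3098, 6290 and 8201 CPM in these libraries, and no error can be drawn with 1 library per group.

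Effector genes were higher in the aged vehicle library than in the young one. Of 25 cytotoxic effector genes, 20 were at least 1.5-fold higher and none lower (median 1.90). NK cell markers were higher with them, in 7 of 10 cases and lower in none (median 1.84), and 3 of these 10 genes also stand in the cytotoxic list. Gzma, a granule protease of both cell kinds, was at 0.537 and 30.2 CPM and Styk1 at 0.610 and 14.9 CPM. Ifng, which encodes interferon gamma, was at 247 CPM in the young and 2012 CPM in the aged vehicle library, a log2 ratio of 3.02 (interval 2.99 to 3.06). Gzmb, a granule protease of killer cells (chromosome 14, 56258838 to 56262260), was at 3098 and 6290 CPM, a log2 ratio of 1.02 that was 0.973 with TMM scaling, and Prf1, the pore-forming perforin, at 65.9 and 301 CPM. Gzmd was at 1.22 and 104 CPM, but Gzmd, Gzme and Gzmf are near-identical copies whose separate levels are uncertain. Among helper cytokines, 16 of 22 were higher and 2 lower (median 1.55), with Il21 at 2.06 and 66.1 CPM and Il22 at 3.97 and 110 CPM. The age-associated T cell list had 10 of 20 members higher and 1 lower (median 0.69), led by S100a6 at 3.76 and 146 CPM and Ccl5, a chemokine of effector cells, at 10.2 and 282 CPM. The lower member was Tox, at 23.3 and 9.62 CPM, and Pdcd1 was at 76.7 and 68.7 CPM. In the fumarate library Tox and Pdcd1 were at 6.57 and 58.3 CPM. Both genes stand in this list and in the exhaustion list. Inhibitory receptor and exhaustion genes went both ways, with 10 of 20 higher and 5 lower (median 0.50, or 0.006 with a mean of at least 10 CPM). Havcr2, the receptor TIM-3, was at 2.56 and 49.2 CPM, whereas Nrn1, which encodes neuritin (chromosome 13, 36725361 to 36735131), was at 262 and 20.9 CPM (log2 ratio −3.59, interval −3.80 to −3.50).

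The medians of the CD4 lineage and naive lists were below 0 in aged vehicle over young, though most members lay within 1.5-fold. The CD4 lineage list had 3 of 7 members lower and none higher (median −0.48), with Cd40lg, the CD40 ligand, at 50.5 and 10.7 CPM and Trat1, a T cell receptor adaptor, at 12.4 and 0.348 CPM. Cd4 itself was at 238 and 180 CPM and Cd8a at 229 and 187 CPM. The naive and quiescence list had 6 of 20 members lower, 3 higher and 11 within 1.5-fold, and its median of −0.28 turned to 0.0522 when libraries were scaled to the T cell identity list. Ccr7, a lymph node homing receptor, was at 1165 and 412 CPM, Dapl1 at 135 and 22.9 CPM and Tcf7, a transcription factor of naive and memory cells, at 167 and 93.3 CPM, while Il7r, the receptor for interleukin 7, was higher at 75.9 against 48.2 CPM.

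Several metabolic lists were lower in the aged vehicle library. Of 24 glycolysis genes, 16 were at least 1.5-fold lower and none higher (median −0.69), and of 28 hypoxia and HIF targets 19 were lower and 1 higher (median −0.84). Ldha, lactate dehydrogenase A, was at 3809 CPM in the young and 2360 CPM in the aged vehicle library. Pdk1, a kinase that restrains pyruvate dehydrogenase, was at 211 and 65.1 CPM, and Hk2, hexokinase 2, at 313 and 316 CPM. The integrated stress response list had 16 of 27 members lower and 3 higher (median −0.64), the serine and one-carbon list 7 of 17 lower (median −0.43) and the cholesterol synthesis list 6 of 23 lower (median −0.47). Phgdh, the first enzyme of serine synthesis, was at 401 and 176 CPM. The S phase list had a median of −0.44, and the mitosis list one of −0.31, which turned to 0.0173 with scaling to the T cell identity list. The 13 mitochondrially encoded transcripts were higher (median 0.66, 9 past 1.5-fold), while the 28 tricarboxylic acid cycle genes had a median of −0.11, inside the range of random lists. NRF2 targets, genes of the response to oxidants, were higher in 18 of 32 cases and lower in 1 (median 0.65). Nqo1, a quinone reductase, was at 1.76 and 33.7 CPM and Gclm, a subunit of the enzyme that starts glutathione synthesis, at 43.7 and 178 CPM. Of 44 lists with a percentile, 20 lay above and 14 below the central 95% of random lists, against 2.2 for lists of randomly drawn genes. Genes of a list can vary together between any 2 single libraries, so this number does not measure chance differences between libraries.

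The comparison of aged fumarate with aged vehicle cells asks how cells of treated aged mice differed. In the fumarate library 46 genes were at least 2-fold higher and 1045 at least 2-fold lower. All 11 erythroid and platelet markers were lower (median −3.18), as were 9 of 10 basophil and mast cell markers (median −2.08), 7 of 12 B cell markers (median −1.59, or −0.25 and inside the range of random lists with no minimum) and 9 of 10 macrophage and monocyte markers (median −1.09). Pf4 was at 468 CPM with vehicle and 51.3 CPM with fumarate, Gata2 at 113 and 16.2 CPM, and Hbb-bs, a beta globin, at 43.4 and 1.35 CPM. Other genes with the lowest ratios were Serpina3g, a serine protease inhibitor, at 929 and 65.3 CPM (log2 ratio −3.81, interval −3.93 to −3.73), Car2, carbonic anhydrase 2, at 101 and 6.35 CPM, and Aldh1a1 at 85.6 and 5.49 CPM. Serpina3g has near-identical neighbours, so its level is uncertain. Igfbp5 was at 46.5 CPM with vehicle and was listed at 0 CPM with fumarate. The T cell identity list was higher with fumarate by a median of 0.22, with none of its 18 members past 1.5-fold.

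Interferon response genes were lower in the fumarate library in 33 of 44 cases and higher in none, with a median of −1.21. In aged vehicle over young 21 of the 44 were higher and 5 lower (median 0.45, or 0.0895 and inside the range of random lists with a mean of at least 10 CPM). Cxcl9, an interferon-induced chemokine (chromosome 5, 92321347 to 92328079), was at 65.9 CPM with vehicle and 1.44 CPM with fumarate, and Oasl2 was at 57.5 and 4.84 CPM. Iigp1, an interferon-inducible GTPase (chromosome 18, 60376027 to 60392634), was at 251 and 35.7 CPM, against 198 CPM in the young library. Ifng was at 2012 CPM with vehicle and 2268 CPM with fumarate. NRF2 targets were lower in 11 of 32 cases and higher in none (median −0.31), with Nqo1 at 33.7 and 4.91 CPM and Gclm at 178 and 49.6 CPM, in the same pair of libraries in which the markers of other lineages were lower. Both this ratio and the age ratio use the aged vehicle library. Against random lists matched on the ratio of aged vehicle over young, an addition made after seeing the data, the NRF2 median was at percentile 19.0, inside the central 95%, while the interferon median lay below all of them. The basophil and mast cell list (percentile 12.5) and the macrophage and monocyte list (53.1) also lay inside by this measure, whereas the erythroid and platelet list lay below all random lists and the B cell list at percentile 0.01.

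Cytotoxic genes differed less between these libraries than with age. The cytotoxic list's median was 0.17, with 9 of 25 members higher and 2 lower. NK cell markers had 5 of 10 higher and 3 lower (median 0.33, above the range of random lists, but a mean of 0.07 inside it). The cytotoxic median turned to −0.00497 with scaling to the T cell identity list. Gzmb was at 6290 and 8201 CPM, Prf1 at 301 and 465 CPM and Klrk1, the receptor NKG2D, at 64.2 and 119 CPM, while Xcl1 was lower at 65.4 and 35.6 CPM. The CD8 lineage list had 3 of 10 members higher and 1 lower (median 0.39). The higher ones, Klrk1, Klrd1 and Eomes, also stand in the cytotoxic list, and Cd8a was at 187 and 218 CPM. Helper cytokines were lower in 8 of 22 cases and higher in 2 (median −0.34), with a mean of −0.39 that lay inside the range of random lists, and with Il10 at 43.7 and 13.2 CPM and Il17a at 22.4 and 10.3 CPM. Age-associated genes were lower in 8 of 20 cases and higher in 1 (median −0.52), and inhibitory receptor and exhaustion genes were lower in 7 of 20 and higher in 2 (median −0.27, mean −0.28 and inside the range of random lists), including Havcr2 at 49.2 and 25.2 CPM. When matched on the ratio of aged vehicle over young, the age-associated (percentile 7.22), exhaustion (26.2) and helper cytokine (93.8) medians lay inside the range of random lists, and the cytotoxic, NK, CD8 lineage and naive medians above it. Lag3, an inhibitory receptor, was at 164 and 99.8 CPM. Among naive and quiescence genes 4 were higher and 4 lower (median 0.29), and Tcf7 was at 93.3 and 150 CPM.

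Glycolysis genes had a median of 0.36 over vehicle, with 5 of 24 higher and 2 lower, and hypoxia and HIF targets one of 0.39, with 3 of 28 higher and 1 lower. Ldha was at 2360 CPM with vehicle and 3152 CPM with fumarate, and Slc16a3, a lactate exporter, at 166 and 328 CPM, while the glucose transporter gene Slc2a3 was lower at 194 and 83.4 CPM. The tricarboxylic acid cycle list had a median of 0.01 and a mean of −0.04, and the complex I list a median of −0.02, both medians inside the range of random lists. The 13 mitochondrially encoded transcripts had a median of −0.26, below that range, with all 13 within 1.5-fold. Matched on the ratio of aged vehicle over young, their median lay inside the range (percentile 58.9). Fh1, fumarate hydratase, was at 68.1 and 65.9 CPM, a log2 ratio of −0.05 with an interval of −0.17 to 0.08. The mitophagy and autophagy list had 6 of 21 members lower and 1 higher (median −0.29), and its mean of −0.33 lay inside the range of random lists. Matched on the ratio of aged vehicle over young, the T cell identity, glycolysis, HIF and mitosis medians lay above the range of random lists (percentiles of 99.61, 99.87, 100 and 98.4), the S phase median inside it (88.1) and the mitophagy median below it (1.99). Pink1, a kinase that starts mitophagy, was at 23.2 and 13.1 CPM. S phase and mitosis genes had medians of 0.15 and 0.17, which turned to −0.0252 and −0.00985 with scaling to the T cell identity list. The 46 genes higher with fumarate included Klra1 and Klra3, members of a family of near-identical killer cell receptors and therefore uncertain, and Abca1, a cholesterol exporter, at 2.14 and 8.66 CPM. With an added constant of 5 CPM in place of 1, 11 genes were higher and 489 lower, and with at least 10 CPM required in the young library 7 were higher and 147 lower.

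**Figure D2:**
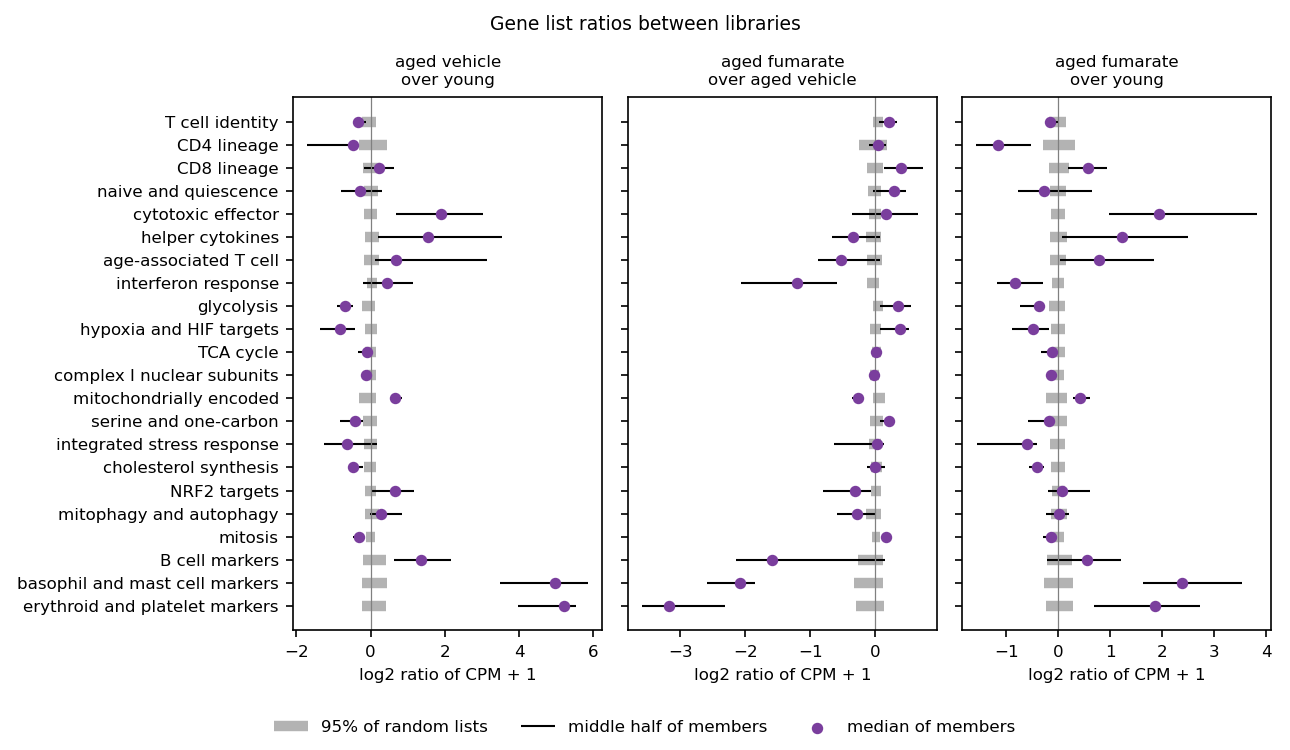
Median log2 ratio of CPM + 1 per gene list in the 3 comparisons (points), the interquartile range of the members (lines) and the central 95% of random lists matched on expression (grey bars). Erythroid and platelet markers had medians of 5.21, −3.18 and 1.85. Among the medians shown outside the central 95% of random lists, scaling to the T cell identity list turned the sign for naive and quiescence, complex I and mitosis (aged vehicle over young), for cytotoxic effector and mitosis (fumarate over vehicle) and for tricarboxylic acid cycle, complex I and mitosis (fumarate over young). Sign changes of medians inside that range were not counted.

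Set against the young library, the aged fumarate library had 710 genes at least 2-fold higher and 347 at least 2-fold lower. Cytotoxic genes were higher in 21 of 25 cases and lower in none (median 1.94), and NK cell markers in 9 of 10 and lower in none (median 1.75). Gzmb was at 3098 and 8201 CPM, Ifng at 247 and 2268 CPM and Prf1 at 65.9 and 465 CPM. Helper cytokines were higher in 14 of 22 cases and lower in 3 (median 1.22), including Il24 at 3.46 and 120 CPM. The CD8 lineage list was higher (median 0.57, 5 of 10 members past 1.5-fold) and the CD4 lineage list lower (median −1.16, 5 of 7), with Cd40lg at 50.5 and 13.4 CPM. Cd8a itself was at 229 and 218 CPM and Cd4 at 238 and 181 CPM. Klrd1 and Nkg7, past 1.5-fold in the CD8 lineage list, also stand in the cytotoxic list. Interferon response genes were lower in 30 of 44 cases and higher in 3 (median −0.84), with Gbp2 at 400.3 and 96.0 CPM. Glycolysis genes were lower in 7 of 24 cases (median −0.38), hypoxia and HIF targets in 13 of 28, with 1 higher (median −0.48) and integrated stress response genes in 16 of 27 (median −0.61). The NRF2 list had 10 of 32 members higher and 1 lower (median 0.07, inside the range of random lists), and Nrn1 was at 262 and 23.5 CPM. Mitochondrially encoded transcripts had a median of 0.41, above the range of random lists, with 4 of 13 past 1.5-fold. Of the erythroid and platelet markers 8 of 11, and of the basophil and mast cell markers 9 of 10, were still higher than in the young library and none lower, with medians of 1.85 and 2.37. With at least 200 estimated reads over both libraries 338 genes were higher and 263 lower, so that 56.2% of these genes were higher against 67.2% with no minimum.

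The 3 libraries were then compared together. Of the 1595 genes higher in aged vehicle over young, 898 were lower in fumarate over vehicle, where independent lists of these sizes would share 93.7, but both ratios use the aged vehicle library and part of the excess may come from that. Of the 304 genes lower in aged vehicle over young, 10 were higher in fumarate over vehicle, out of 46 higher in all, where independent lists would share 0.786, with the same shared library. Across 9624 genes with a mean of at least 10 CPM, the age ratio and the fumarate ratio had a Pearson correlation of −0.75 and a covariance of −0.29. Simulated libraries with no effect gave −0.56 and −0.0032 with counting error alone, and −0.50 and −0.088 with an extra spread of 0.3 per library, so a negative value arises from the shared library itself. Genes are not independent replicates, and the true spread between mice is unknown.

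Among 2298 genes whose highest and lowest library differed at least 2-fold, the aged vehicle library was the one farthest from the other libraries for 1121 genes (1080 of them above), the young library for 988 and the fumarate library for 189. The order of aged vehicle and young depended on the filter: with the planned minimum of 50 reads the aged vehicle library took 898 and the young 935 genes, and with a mean of at least 10 CPM 319 and 492. Gzmd, Ccl9 and Il24 set the young library apart, with Ccl9, a chemokine, at 17.2 CPM in the young, 469 CPM in the vehicle and 453 CPM in the fumarate library. Cxcl9 and Serpina3g set the aged vehicle library apart, and Mpeg1, Iigp1, Isg15 and Irf7 the fumarate library. Irf7, a transcription factor of interferon responses, was at 17.7, 28.8 and 4.04 CPM in the young, vehicle and fumarate libraries.

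**Figure D3:**
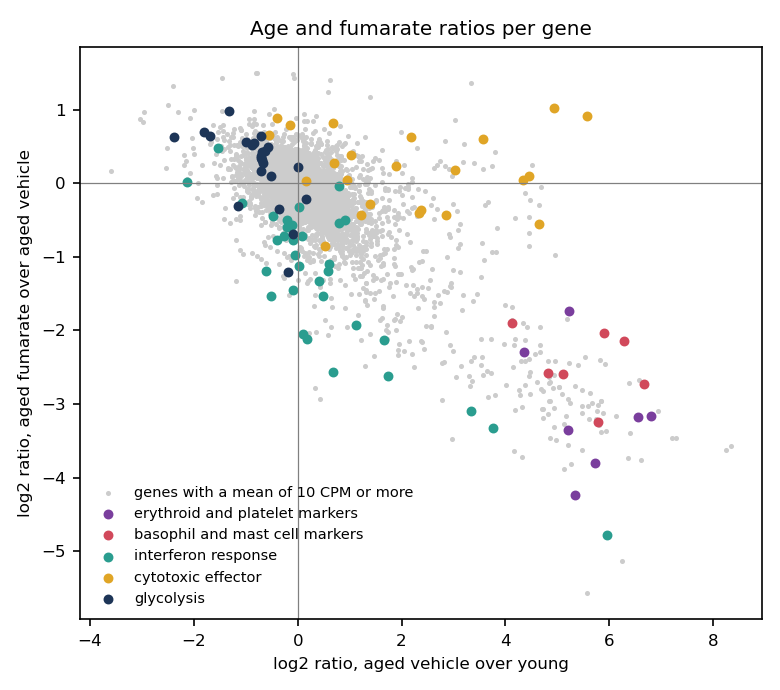
Log2 ratio of aged vehicle over young (x axis) against log2 ratio of aged fumarate over aged vehicle (y axis) for 9624 genes with a mean of at least 10 CPM, with 1 point per gene and 5 gene lists in colour. Both axes use the aged vehicle library, which alone gives a negative slope, and the cytotoxic list's median on the y axis (0.17) turned to −0.00497 with scaling to the T cell identity list.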

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

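No paired analysis was possible because each group has 1 library and no result comes from a test across replicates. TMM, median-of-ratios and upper-quartile scaling, the minimum of 50 reads, protein-coding genes alone, thinning and leaving out receptor segments, mitochondrial and ribosomal protein genes kept the 6 gene counts within 1.5 times. Chosen after seeing the data were protein-coding genes alone, scaling to the T cell identity list and, for the gene counts and the library that stands apart, constants of 0.5 or 5 CPM and minimums of 10 CPM. Of 1296 list medians recomputed, 35 came to lie inside the limits of random lists and 8 outside. Another 13, outside these limits in the main setting, changed sign. Of 918 ratios of named genes, 14 fell below 2-fold and 3 passed it, and none that was at least 2-fold in the main setting changed sign. Sign changes of smaller ratios and of medians inside the limits were not counted, and scaling to the T cell identity list can turn these too. Where no construction is named, the cause was not tested. Depth limits low genes: in the fumarate library 1 read is worth 0.0722 CPM, and in the young 0.0244 CPM.

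Counts are given as higher and lower for aged vehicle over young, then fumarate over vehicle, then fumarate over young. The larger constant, the higher limit and the minimums lower them by construction. With a constant of 5 CPM they were 851 and 142, 11 and 489, and 298 and 142. With a 3-fold limit they were 918 and 73, 9 and 539, and 319 and 98. With at least 10 CPM in the library not compared they were 469 and 124, 7 and 147, and 469 and 131. With at least 200 reads they were 867 and 236, 18 and 511, and 338 and 263. A constant of 0.5 CPM raised the genes higher for fumarate over vehicle to 116, against 46. Scaling to the T cell identity list removes no genes but moves every ratio of aged vehicle over young up, and left 169 lower there, against 304.

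The library that stands apart was young, aged vehicle and fumarate for 488, 590 and 69 genes with a constant of 5 CPM, for 428, 653 and 47 with a 3-fold limit, and for 492, 319 and 81 with a mean of at least 10 CPM. With at least 200 reads these were 685, 514 and 115, so that the order of young and vehicle turned against 988 and 1121, as it did with a mean of at least 10 CPM. A constant of 0.5 CPM gave 297 for fumarate. The correlation of the age and fumarate ratios was −0.63 with a mean of at least 50 CPM, against −0.75. A shift above 0.05, a tolerance chosen for want of replicates, counted as moved.

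Values are divided by a factor per library, which with scaling to the T cell identity list was −0.33 for aged vehicle and −0.16 for fumarate against young on the log2 scale, and 0.0999 or less with the other scalings. Medians changed sign by this construction. For aged vehicle over young they became 0.0522 for naive and quiescence, 0.102 for activation and costimulation, 0.206 for complex I, 0.0173 for mitosis and 0.0333 for DNA methylation and histone demethylation. For fumarate over vehicle they became −0.00497 for cytotoxic effector, −0.0252 for S phase and −0.00985 for mitosis. For fumarate over young they became 0.0259 for the tricarboxylic acid cycle, 0.00480 for complex I, 0.0198 for complexes III to V and 0.0233 for mitosis. With a mean of at least 10 CPM the inhibitory receptor and exhaustion list for fumarate over young became −0.38, against 0.51. A separate comparison, also chosen after seeing the data and not among the recomputed medians, used random lists matched on the ratio of aged vehicle over young. The fumarate over vehicle medians of NRF2 (percentile 19.0), age-associated (7.22), exhaustion (26.2), helper cytokine (93.8), basophil and mast cell (12.5), macrophage and monocyte (53.1) and S phase (88.1) lists lay inside the random range.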

Other observations

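Every test of an explanation below was chosen after the result was seen, except the count of markers at whole reads. T cell receptor beta variable segments gave another view of the cells. Trbv13-2 held 9.76% of beta variable reads in the young library (95% Clopper-Pearson interval 9.01 to 10.6), 17.3% in the aged vehicle (15.7 to 18.9) and 18.6% in the aged fumarate library (16.9 to 20.4). Trbv3 held 9.34% (8.6 to 10.1), 13.7% (12.3 to 15.3) and 8.12% (6.95 to 9.43), and Trbv19 8.48% (7.78 to 9.23), 8.66% (7.51 to 9.92) and 12.4% (11 to 13.9) in the same order, so the aged libraries differed from each other in both. These segments were chosen after their values were seen, such segments have close copies, and the intervals cover counting error alone. Immunoglobulin variable segments summed to 2.42 CPM in the young, 84.1 CPM in the vehicle and 16.8 CPM in the fumarate library, and all immunoglobulin genes to 144, 549 and 120 CPM, of which Ighm alone was 135, 212 and 54.1 CPM. Unfolded protein response genes were higher in 5 of 21 cases in aged vehicle over young (median 0.40), with Calr, a chaperone of the endoplasmic reticulum, at 709 and 1372 CPM. Of 16 senescence genes, 8 were higher and 2 lower in aged vehicle over young (median 0.56, or 0.231 and inside the range of random lists with a mean of at least 10 CPM), and 9 higher and 2 lower in fumarate over young (median 0.75). Cdkn2a, a cell cycle inhibitor, was at 0.512 CPM in the young, 13.6 CPM in the vehicle and 5.27 CPM in the fumarate library. Of 17 genes of DNA methylation and histone demethylation, 1 was higher and 2 lower in aged vehicle over young (median −0.30, below random lists but 0.0333 with scaling to the T cell identity list). Dnmt3b, the higher one, was at 17.0 CPM in the young, 27.6 CPM in the vehicle and 7.87 CPM in the fumarate library, whereas Tet1 was at 5.93 and 1.22 CPM and Ezh2 at 284 and 180 CPM in the young and vehicle libraries. Scd1 and Scd2, fatty acid desaturases, were at 178 and 1445 CPM in the young and 33.1 and 608 CPM in the vehicle library. They were the 2 lower of 15 measured fatty acid synthesis genes, of which 2 were higher and 11 within 1.5-fold. That list had a median of −0.17, inside the range of random lists.

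The most prominent pattern was transcripts of other blood lineages in the aged vehicle library. Erythroid and platelet markers summed to 1287 CPM there, against 11.8 in the young and 157 in the fumarate library, and 3 of the 11 were at 1 CPM or more in the young. The marker median over young was 5.13 after thinning, but thinning keeps the expected CPM ratio, so this could not decide on a difference in depth. The young library, where these markers were lowest, had the highest estimated depth. Reads divided between copies were argued against only for the 14 of 21 markers that sat at whole reads and were at least 2-fold higher. Over all genes of that library 66.1% sat at whole reads, so the count does not set the markers apart from other genes. Cells of other types in that culture are a candidate explanation: the T cell identity list was higher in fumarate over vehicle (0.22), which such cells would give, and the labels name T cells but no sort. A difference with age or fumarate, a difference between mice or spleens, culture and a mislabelled library stay open with 1 library per group.

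Glycolysis and HIF targets were lower in aged vehicle over young (medians −0.69 and −0.84), and their medians were higher in fumarate over vehicle (0.36 and 0.39). In the second comparison 17 of 24 and 24 of 28 members lay within 1.5-fold. Dilution by other cells may add to the difference of aged vehicle over young. In that comparison these genes lay below the T cell identity list by a median difference of −0.36 (bootstrap interval over genes −0.64 to −0.19). This argues against dilution as the whole cause only if T cells of both libraries held equal levels of identity transcripts, which was not measured. The difference from the S phase and mitosis lists was −0.34 (−0.52 to −0.21). That argues against less cell division as the whole cause only if division lowers these genes no further than those lists, which was not tested. For fumarate over vehicle the difference from the T cell identity list was 0.12 (−0.06 to 0.29), so dilution and a change in these genes cannot be told apart there, because the interval includes 0. Age and fumarate remain untested, and genes are not replicates.

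The interferon response list had medians of −1.21 for fumarate over vehicle and −0.84 for fumarate over young. Over young, 30 of 44 genes were lower, 3 higher and 11 within 1.5-fold. Cells of other types in the vehicle culture could account for part of the gap to vehicle, but the median of −0.84 over young does not use that library. Cells of other types in the young culture stay open: B cell markers summed to 261 CPM in the young and 209 CPM in the fumarate library, and macrophage and monocyte markers to 96.1 and 72.5 CPM. Ighm was at 135 and 54.1 CPM and Mpeg1 at 13.4 and 1.52 CPM. The sums rest on few genes, since the medians of these lists over young were 0.55 and 0.65. Of 12 B cell markers 5 were higher and 1 lower over young, and of 10 macrophage and monocyte markers 6 were higher and 1 lower. Less Ifng transcript was argued against by an Ifng log2 ratio over young of 3.19 (3.17 to 3.23). This covers the Ifng transcript alone, and secreted protein and other interferons were not tested. The interferon median over young was −0.86 after thinning, which keeps the expected CPM ratio and so could not decide on depth. An effect of fumarate, a difference between mice and culture also stay open.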
